A study of Mus musculus with 9 samples.

How the data were processed

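RNA was sequenced from 9 libraries of mouse spleen T cells, 3 libraries in each of 3 groups. Per the labels' protocols, CD4+ T cells of C57BL/6 mice carrying a surface marker of naive cells were purified on magnetic beads. Activated cells received plate-bound antibodies against CD3 and CD28, after 15 min with DMSO or with TEPP-46. The labels give the TEPP-46 concentration as a range of 50 to 100 µM for the treatment and not per library, and the length of activation is not given in the sources used here. Nor is it given there whether the resting cells were cultured or taken directly after isolation. Total RNA was extracted with the PureLink RNA Mini kit and quantified on a Qubit instrument. Libraries were made with a NEBNext low-input kit and run on a HiSeq instrument, per the labels' protocols.

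The authors deposited raw read counts per gene for each library, as whole numbers without normalization, in a single table headed by the sample titles. The mouse genome build GRCm38 and DESeq2 are named in the submitters' processing notes, without a version of DESeq2. The aligner, the counting program, the strand setting and the annotation release are not given in the sources used here. The table holds 47937 Ensembl gene identifiers, of which 47224 were paired with a symbol from the GENCODE M21 annotation of GRCm38 and 713 were not. For 39106 identifiers the version number matched exactly. Coordinates are those of GENCODE M21 on GRCm38, counted from 1. The strand of counting is unknown, so reads of a gene and of an overlapping antisense partner cannot be told apart. Malat1 overlaps the predicted gene Gm37376. Immunoglobulin variable genes, Hspa1a and Hspa1b, Trbc1 and Trbc2, Rn7sk and Ifit1bl1 share sequence with near-identical copies, so their counts are uncertain.

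Total counts per library ran from 2397304 to 5030643, and a floor of 3 counts corresponded to between 0.596 and 1.25 CPM (counts scaled to 1000000 per library) in a library. The reads carry no molecular identifiers used here, so counting intervals and floors cover counting error only. Of 23436 genes with a count in any library, 12536 passed the filterByExpr function of edgeR by group, with a minimum count of 10 and a minimum total of 15. Counts were scaled with TMM factors. All 9 libraries were fitted together by group with the quasi-likelihood functions glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 12536 genes with a threshold of 0.05. The common dispersion was 0.1086, a biological coefficient of variation of 0.33, with 6 residual degrees of freedom. The standard error (SE) of each log2 fold change came from the same fit. CPM values are given on the TMM-scaled library sizes as mean ± SD over 3 libraries, and log2 CPM used a prior count of 2. Levels in CPM are shares of a library and not amounts per cell, as no measure of RNA per cell was used. A fold change against a group without counts was computed against a floor of 3 counts over the whole group. With 1 to 3 counts, the ratio is given with its 95% counting interval.

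A set of 32 gene lists was fixed before the data were examined, together with the grouping, the tests, the other settings tried and the rule for naming genes. The lists covered metabolism, T cell states, stress responses, markers of other spleen cells and RNA quality. The 29 lists with at least 5 genes tested were compared with all other genes by camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists. Camera was run again with a correlation estimated for each list. The self-contained fry test was run as a further check. Changed members were also counted after adjustment over the list alone. The preset genes Pkm, Pklr, Hif1a, Myc, Slc2a1, Hk2, Ldha, Cd69, Il2ra, Il2, Ifng, Il17a, Csf2, Tbx21, Foxp3 and Txnip were reported in every comparison. In each of the 2 main comparisons, the 6 genes with the largest rise and the 6 with the largest fall were named, among genes past the threshold with a mean of at least 10 CPM, no overlap between the libraries of both groups and a symbol that is not a clone or predicted-gene name. From each list, up to 4 members were named in order of adjusted p. Some genes that the rule would name are not reported here. Genes named outside this rule are marked as such.

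The correlation and covariance of the activation and TEPP-46 fold changes were set beside 20 simulations in which TEPP-46 had no effect, because both comparisons use the same 3 control libraries. Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other filters on low counts, a fold change threshold (glmTreat), only the groups compared, the replicate number as a block, and leaving out each library in turn. Library quality weights, thinning to equal totals, removal of a trend on transcript length and GC content, and TMM factors without immunoglobulin genes and the 20 most abundant genes, and a split of the control libraries between the 2 comparisons, in which a lone library is assumed to vary like the other groups, were added after the data had been seen. Replicates were distinct libraries: the chi-square per degree of freedom within groups was between 4.03 and 56.1.

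The gene test was tested on simulated data drawn from these libraries over 12536 genes, with 100 genes changed 2-fold and 100 changed 4-fold. For activation it recovered 3% of the 2-fold and 80% of the 4-fold changes with 2 false calls. For TEPP-46 against control it recovered 5% and 72% with 2 false calls, and for TEPP-46 against resting cells 4% and 72% with 3 false calls. A shifted list was called at an adjusted p of 0.000191 with 0 calls among the other lists, and the overlap step recovered 62 of 100 planted genes with 0 false ones. The simulated genes varied independently of each other, so the list result does not cover lists whose genes move together. Differences of 2-fold were thus mostly missed in this simulation. With so few genes changed, its adjusted threshold is stricter than in the real comparisons. There 31.22% (activation), 16.15% (TEPP-46 against control) and 10.28% (TEPP-46 against resting cells) of genes were called. Recovery of 2-fold changes may be higher there. No library was left out of the comparisons. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and drew the figures.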

Results

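RNA was measured in CD4+ T cells from the spleens of C57BL/6 mice, sorted for a surface marker of naive helper T cells. The 9 libraries formed 3 groups of 3, numbered 1, 4 and 5 in each group. Resting cells were compared with cells activated through the T cell receptor and CD28 in the presence of the solvent DMSO (control cells), and with cells activated in the same way after incubation with TEPP-46 (TEPP-46 cells). Whether the resting cells were cultured or taken directly after isolation is not given in the sources used here. TEPP-46 is a small molecule that activates pyruvate kinase M2, the splice form of the Pkm gene product found in proliferating cells, which carries out the last step of glycolysis. The comparisons ask which transcripts change when naive CD4+ T cells are activated and which of them differ when pyruvate kinase M2 is pharmacologically activated. Total counts were 5030643, 3903124 and 4754814 in the resting libraries (replicates 1, 4 and 5), 3782126, 4043226 and 3773438 in the control libraries, and 3900023, 2397304 and 3234647 in the TEPP-46 libraries. No label states that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Changes below are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p, and levels are in CPM (counts scaled to 1000000 per library, mean ± SD, n = 3). For gene lists, counts within the list are those after adjustment over its genes alone. Beside the camera adjusted p, a value marked estimated is the adjusted p when the correlation between genes was estimated for each list.

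The resting and control libraries lay at opposite ends of the first dimension of expression, and the TEPP-46 libraries were spread between them. On this first dimension of a multidimensional scaling, which held 51.6% of the variance, the resting libraries lay between -2.19 and -1.97 and the control libraries between 2.10 and 2.16. TEPP-46 replicates 1, 5 and 4 lay at 1.15, -0.27 and -1.13. On the second dimension (21.8%) they lay outside both other groups, at -0.38, -1.04 and -2.76 against 0.39 to 1.10. The median SD of log2 CPM over genes was 0.52 among TEPP-46 libraries, against 0.31 among resting and 0.20 among control libraries. Resting replicate 1 stood apart, with a correlation of 0.938 and 0.937 with resting replicates 4 and 5, which correlated at 0.977 with each other. TEPP-46 replicate 4 had the lowest total count, 12290 CPM of the nuclear RNA Malat1 and 5232 summed CPM of cytosolic ribosomal protein genes. Replicate 5 had 12820 and 10350 CPM, replicate 1 had 2532 and 20180 CPM, the control libraries had 2067 to 4120 and 15040 to 18640 CPM, and the resting libraries had 4373 to 8385 and 9399 to 12320 CPM.

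**Figure D1:**
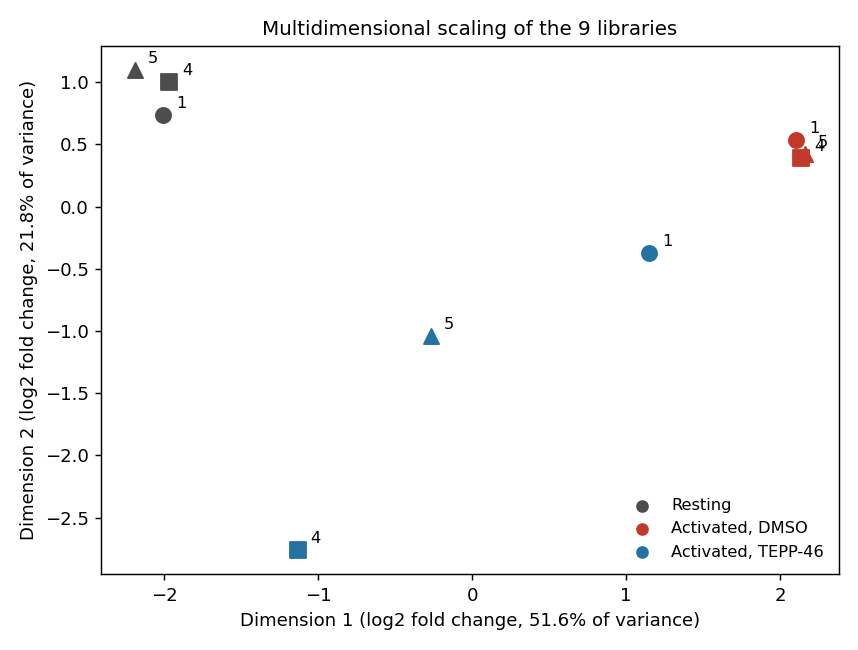
Multidimensional scaling of the 9 libraries on their leading log2 fold changes, with dimension 1 (51.6% of the variance) against dimension 2 (21.8%). Each point is a library, the colour gives the group, and the marker and number give the replicate. TEPP-46 replicate 1 lies at 1.15 on dimension 1, nearest to the control libraries, and replicate 4 at -1.13.

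Activation changed glycolysis and cell division genes in control cells relative to resting cells. Hk2, which encodes a hexokinase of the first step of glycolysis, rose from 2.63 ± 1.92 to 106 ± 9.92 CPM (log2 fold change 5.28 ± 0.50, adjusted p = 0.000174). Slc2a3, a glucose transporter, rose from 90.8 ± 28.5 to 1256 ± 216 CPM (3.79 ± 0.28, adjusted p = 8.24e-05). Pkm itself (ENSMUSG00000032294.16, chromosome 9, 59656368 to 59679375, GRCm38) rose from 1242 ± 219 to 4885 ± 620 CPM (1.98 ± 0.40, adjusted p = 0.00509). Il2ra, the alpha chain of the interleukin-2 receptor, rose from 43.3 ± 19.5 to 1531 ± 110 CPM (5.15 ± 0.51, adjusted p = 0.000226). S1pr1, which guides T cells out of lymphoid organs, fell from 1575 ± 293 to 38.1 ± 16.8 CPM (-5.37 ± 0.51, adjusted p = 0.00019). In all, 1938 genes rose and 1976 fell at an adjusted p below 0.05 among 12536 tested, 1672 and 1437 of them by more than 2-fold. Each gene named as changed had all 3 libraries of a group above all 3 of the other. Such a separation held for 59.2% of all genes, where chance gives 10%. With total counts as the only scaling, 58.2% of the calls were rises instead of 49.5%. Without resting replicate 4 the number of calls was 2590. Without control replicate 1, 4 or 5 it was 2515, 2416 or 2316.

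Among the other preset genes, the glucose transporter Slc2a1 (1.37 ± 0.26, adjusted p = 0.0042), the lactate dehydrogenase gene Ldha (1.82 ± 0.46, adjusted p = 0.0133), Hif1a, which encodes the oxygen-sensitive subunit of a transcription factor that drives glycolytic genes (1.66 ± 0.38, adjusted p = 0.0092), and Tbx21, the Th1 transcription factor T-bet (3.02 ± 0.62, adjusted p = 0.00545), rose. The growth regulator Myc rose with 1.88 ± 0.64 (adjusted p = 0.0464). Txnip, an inhibitor of glucose uptake, fell (-2.07 ± 0.33, adjusted p = 0.0017). So did the early activation marker Cd69 (-1.34 ± 0.40, adjusted p = 0.0283) and Ifng, which encodes interferon gamma (-2.40 ± 0.79, adjusted p = 0.0426). The Treg factor Foxp3 (-0.73 ± 0.31, adjusted p = 0.100) and Il2 (1.61 ± 0.94, adjusted p = 0.217) did not pass the test in edgeR. Pklr and Csf2 had too few counts to be tested, with 68 and 5 counts over the resting libraries and 4 and 25 over the control libraries. Il17a had 0 counts in every library. The values of Ifng and Il2 rest on few reads, with 132 and 14 counts over the resting and 23 and 40 over the control libraries. The calls of Myc and Ifng were lost without any of resting replicates 1 and 5, control replicates 1, 4 and 5 or TEPP-46 replicate 5 (highest adjusted p = 0.153 for each). That of Ifng was also lost without resting replicate 4. The call of Cd69 was lost without resting replicate 4 or 5 or any control library (highest adjusted p = 0.107).

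The rises ranked largest by log2 fold change included several genes that were nearly silent in resting cells. Fam71b (0 counts in resting cells, at least 143-fold higher), the lipoprotein receptor gene Vldlr (at least 127-fold) and the lipase gene Lipg (at least 96.4-fold) had no resting counts, with edgeR adjusted p of 0.00034, 0.00151 and 0.00169. The transcription factor gene Batf3 was 911 times higher (95% counting interval 163 to 36000, adjusted p = 0.00025) and the laminin gene Lama5 210 times (71.4 to 1020, adjusted p = 0.00019). Stc2, a secreted stress-induced glycoprotein gene, rose by 7.53 ± 1.04 on the log2 scale (adjusted p = 0.000999). The largest falls were in genes of antibody-producing cells and granulocyte precursors. Igha, the IgA heavy chain gene, was 12000 times lower (2150 to 473000, adjusted p = 0.000167). The immunoglobulin light chain genes Igkv6-23, Iglv2, Igkv8-27 and Igkv12-46 were at least 360-, 335-, 310- and 251-fold lower, with edgeR adjusted p of 0.00152, 0.00477, 0.000226 and 0.0086. Mpo, the myeloperoxidase gene of granulocyte precursors, was at least 357-fold lower (adjusted p = 0.0102).

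Of the 22 glycolysis genes tested, 20 rose and 0 fell (21 rose when within the list), with a median log2 fold change of 2.18 (camera adjusted p = 3.98e-15, 0.24 estimated). Pgam1 and Gpi1, which encode enzymes of the pathway, rose by 2.96 ± 0.33 and 2.11 ± 0.26. In the hypoxia list, 13 of 17 genes rose and 0 fell (13 within the list, median 2.27, camera adjusted p = 5.26e-09, 0.24 estimated). In order of adjusted p it was led by the prolyl hydroxylase gene Egln3 (5.87 ± 0.51, from 2.92 ± 1.56 to 177 ± 23.5 CPM) and the oxidoreductase gene Ero1l (3.79 ± 0.35). Of 31 cell division genes, 26 rose and 0 fell (29 within the list, median 3.55, camera adjusted p = 2.69e-13, 0.43 estimated). The proliferation marker Mki67 rose from 11.1 ± 0.32 to 311 ± 17.8 CPM (4.80 ± 0.70). The mitotic genes Cenpf and Aurkb rose by 4.76 ± 0.67 and 4.56 ± 0.65. The amino acid response list (targets of ATF4) had 19 of 24 genes higher and 0 lower (21 within the list, median 1.70, camera adjusted p = 5.91e-09, 0.401 estimated). The stress regulator Nupr1 (6.22 ± 0.84) and the arginine transporter Slc7a3 (5.22 ± 0.72) were among them. Cholesterol synthesis genes rose in 15 of 22 cases with 0 falls (20 within the list, median 1.85, camera adjusted p = 1.4e-07, 0.43 estimated). The sterol carrier gene Stard4 rose by 2.41 ± 0.40. In the list of serine, folate and nucleotide synthesis, 12 of 21 rose and 0 fell (14 within the list, median 1.10, camera adjusted p = 2.62e-05, 0.473 estimated). The mitochondrial folate enzyme gene Mthfd2 stood at 2.16 ± 0.45 and Shmt1 at 2.27 ± 0.41.

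T cell state genes changed in both directions. Of 24 naive and quiescence genes, 16 fell and 0 rose (18 within the list, median -1.79, camera adjusted p = 6.25e-11, 0.111 estimated). The transcription factor gene Klf3 (-2.76 ± 0.27), the quiescence gene Slfn2 (-2.52 ± 0.29) and the antiproliferative gene Btg2 (-2.52 ± 0.33) fell. Interleukin-2 and STAT5 targets rose in 13 of 17 cases and fell in 1 (13 and 1 within the list, median 1.46, camera adjusted p = 9.57e-08, 0.24 estimated). The signalling inhibitor Socs2 rose by 4.46 ± 0.40. Of 10 cytokine and chemokine genes, 6 rose and 2 fell (7 and 2 within the list, median 1.87, camera adjusted p = 0.00589, 0.401 estimated). Lymphotoxin alpha (Lta) rose from 25.2 ± 8.15 to 1023 ± 512 CPM (5.34 ± 0.49) and the granzyme gene Gzmb by 7.02 ± 0.86. Inhibitory receptor and anergy genes rose in 7 and fell in 2 of 15 cases (8 and 3 within the list, median 1.10, camera adjusted p = 0.0073, 0.24 estimated). Their largest rise was in Lag3, an inhibitory receptor of activated T cells, from 15.4 ± 6.30 to 858 ± 155 CPM (5.80 ± 0.37), while the diacylglycerol kinase gene Dgka fell (-2.25 ± 0.30). Early activation genes were split, with 12 rises and 7 falls among 27 (13 and 7 within the list, camera adjusted p = 0.0756). The transferrin receptor gene Tfrc rose by 3.35 ± 0.44, whereas the immediate-early genes Fosb (-6.20 ± 0.69) and Jun (-3.47 ± 0.41) fell. Treg genes rose in 5 and fell in 1 of 14 cases (5 and 1 within the list, median 0.65, camera adjusted p = 0.0361, 0.24 estimated). Ebi3 rose by 3.03 ± 0.47. The p53 and apoptosis list had 9 rises and 2 falls among 19 (9 and 2 within the list, median 0.77, camera adjusted p = 0.00363, 0.43 estimated). The cell cycle inhibitor Cdkn1a rose by 4.37 ± 0.81. The Treg list lost its camera call without resting replicate 5 or TEPP-46 replicate 5 (adjusted p up to 0.0619), and the inhibitory receptor list without TEPP-46 replicate 1 (adjusted p = 0.0526).

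Another 9 lists, of metabolism, T cell subsets and stress, did not pass camera in this comparison. Of 26 genes of MYC-linked ribosome biogenesis, 2 rose and 0 fell (0 within the list, median 0.09, camera adjusted p = 0.518). Those were Myc and the nucleolar gene Npm1, the latter lost without any resting or control library (highest adjusted p = 0.128). Oxidative phosphorylation had 3 rises among 32 genes (0 within the list, camera adjusted p = 0.302), and the TCA cycle 3 rises and 2 falls among 21 (1 and 0 within the list, camera adjusted p = 0.337). Th1 genes split into 4 rises and 5 falls among 14 (4 and 5 within the list, camera adjusted p = 0.942). Runx3 rose (2.10 ± 0.30) and the chemokine receptor gene Cxcr3 fell (-2.67 ± 0.35). Th17 genes had 2 rises and 1 fall among 7 (3 and 1 within the list). Their median and mean were -0.33 and -0.03 but the camera direction was up (adjusted p = 0.70). Type I interferon genes had 1 rise and 6 falls among 24 (1 and 6 within the list, camera adjusted p = 0.275), including the interferon signalling gene Irf9 (-1.21 ± 0.19). The oxidative stress list had 2 rises and 3 falls among 17, the heat shock and unfolded protein list 2 rises and 3 falls among 21, and the xenobiotic list 0 rises and 2 falls among 6, with the same counts within the list and camera adjusted p of 0.563, 0.563 and 0.598. The median of the heat shock list was 0.33 and its mean -0.12, with camera pointing down.

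In camera, markers of B cells and NK cells were lower as lists in control than in resting libraries, while those of myeloid cells did not pass. Of 15 B cell markers, 6 fell and 0 rose (8 within the list, median -2.90, camera adjusted p = 0.00236, 0.582 estimated). Their summed CPM was 3745 ± 529 in resting and 820 ± 144 in control libraries. The IgM heavy chain gene Ighm fell from 1712 ± 89.0 to 230 ± 11.3 CPM (-2.90 ± 0.20) and the kappa chain gene Igkc from 1413 ± 668 to 3.60 ± 0.21 CPM (-8.60 ± 1.11). NK cell markers fell in 3 of 5 cases with 0 rises (4 within the list, median -3.54, camera adjusted p = 0.0339, 0.401 estimated). This camera call was lost without resting replicate 5 or TEPP-46 replicate 1 (adjusted p up to 0.0562). Myeloid markers had 2 rises and 4 falls among 10 (2 and 5 within the list, camera adjusted p = 0.303), with the lysozyme gene Lyz2 at -5.70 ± 0.88. T cell identity genes fell in 6 of 16 cases with 0 rises (6 within the list, median -0.61, camera adjusted p = 0.0233, 0.632 estimated), led by the receptor signalling chain Cd247 (-1.94 ± 0.26). The camera call was lost without resting replicate 4 or control replicate 1 (adjusted p up to 0.0721). Among 2 neutrophil, 1 CD8 and 2 platelet and red cell markers tested, 0 passed in edgeR, DESeq2 or limma-voom, also within the list (1, 0 and 0 at an unadjusted p below 0.05). Mitochondrially encoded genes had 1 rise and 3 falls among 7, and histone genes 0 and 1 among 5. Cytosolic ribosomal protein genes had 0 and 0 among 24 in edgeR (2 at an unadjusted p below 0.05, 1 in DESeq2 and 0 in limma-voom). These counts were the same within the list, with camera adjusted p of 0.275, 0.417 and 0.0858. In all, camera called 15 of 29 lists, 11 up and 4 down. With an estimated correlation 0 held (6 at an unadjusted p below 0.05). The fry test, which asks whether the genes of a list move on balance in a single direction, called 14. It did not call the B cell and T cell identity lists (adjusted p of 0.0757 and 0.0531). In turn, it called the early activation list up (fry adjusted p = 0.0233), which camera did not call.

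With TEPP-46, activated cells had lower levels of 7 of 22 glycolytic and 10 of 17 hypoxia-response genes than control cells, and higher levels of 13 of 24 naive-state genes. The camera calls of these lists did not hold with an estimated correlation (adjusted p of 0.33, 0.266 and 0.171). Slc2a3 fell from 1256 ± 216 to 347 ± 13.2 CPM (-1.86 ± 0.26, adjusted p = 0.00288) and Hk2 from 106 ± 9.92 to 21.9 ± 9.37 CPM (-2.27 ± 0.42, adjusted p = 0.00865). Lta fell from 1023 ± 512 to 26.8 ± 11.6 CPM (-5.24 ± 0.49, adjusted p = 0.000736), close to its 25.2 CPM in resting cells. S1pr1 rose from 38.1 ± 16.8 to 563 ± 280 CPM (3.88 ± 0.48, adjusted p = 0.00209). In all, 1219 genes rose and 806 fell among 12536 tested, 985 and 660 by more than 2-fold, 2025 calls together against 3057 with DESeq2. The libraries of both groups were fully separated in 39.7% of genes, where chance gives 10%. Each gene named as changed was separated in this way, except Itgae. Of these calls 60.2% were rises, against 43.8% (922 rises and 1182 falls) with total counts as the only scaling and 47.6% with limma-voom. The median change of all genes moved from 0.04 to -0.09 (log2) with total counts. The number of calls was 592, 535 or 395 without control replicate 1, 4 or 5, 647 without TEPP-46 replicate 5 and 4407 without TEPP-46 replicate 1.

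The target transcript Pkm did not differ by the test: it stood at 4994, 1549 and 2212 CPM in TEPP-46 replicates 1, 4 and 5 (-0.74 ± 0.39, adjusted p = 0.201). Txnip rose (1.95 ± 0.33, adjusted p = 0.00606) to 261 ± 77.7 CPM, and Foxp3 rose (1.18 ± 0.32, adjusted p = 0.0321) from 29.8 ± 3.90 to 44.8, 76.5 and 81.9 CPM in TEPP-46 replicates 1, 4 and 5. Il2ra fell (-1.70 ± 0.44, adjusted p = 0.0288) from 1531 ± 110 to 472 ± 313 CPM, and Myc fell (-2.17 ± 0.65, adjusted p = 0.0455) from 671 ± 266 to 149 ± 123 CPM. Hif1a stood at 1928 ± 813 against 848 ± 223 CPM (1.18 ± 0.38) and missed the threshold in edgeR (adjusted p = 0.0563). Slc2a1 (-0.65 ± 0.26, adjusted p = 0.108), Ldha (-0.78 ± 0.44, adjusted p = 0.238), Cd69 (-0.30 ± 0.39, adjusted p = 0.616), Tbx21 (0.64 ± 0.56, adjusted p = 0.443), Il2 (-0.64 ± 0.92, adjusted p = 0.654) and Ifng (-0.05 ± 0.88, adjusted p = 0.976) did not pass either. Pklr and Csf2 had 0 and 4 counts over the TEPP-46 libraries. Ifng and Il2 had 18 counts each over these libraries, so their changes rest on few reads. The calls of Myc, Il2ra and Foxp3 were lost without any control library or TEPP-46 replicate 4 or 5 (highest adjusted p of 0.153, 0.11 and 0.122), and that of Myc also without resting replicate 4 or 5. Those of Hk2, Slc2a3, Lta, S1pr1 and Txnip held in all 9 fits that left out a library.

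**Figure D2:**
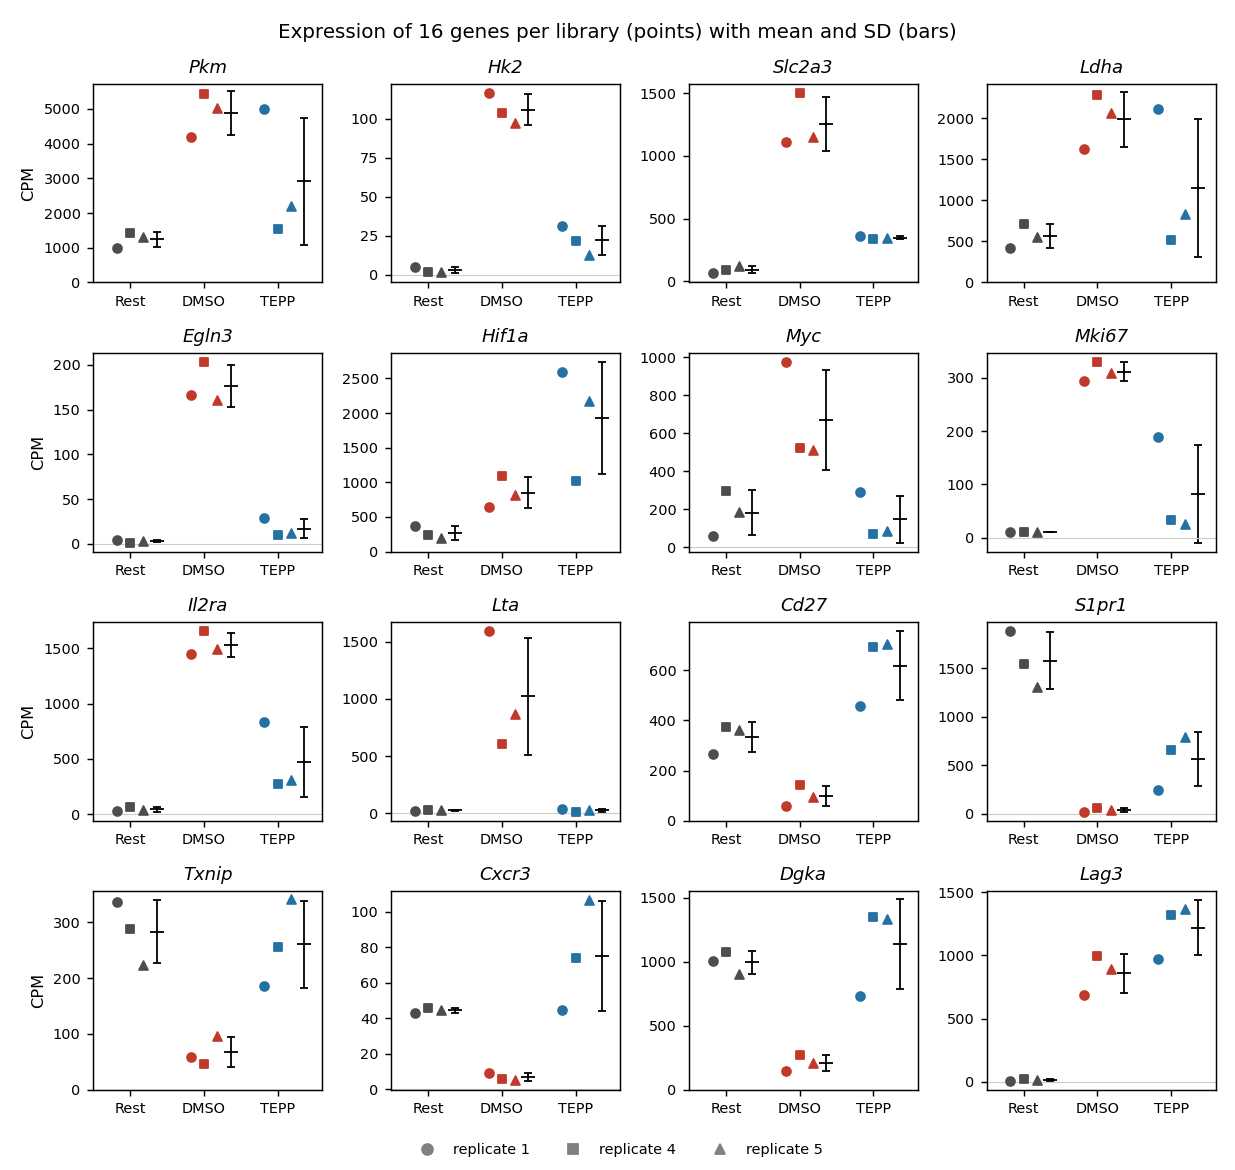
Expression of 16 genes in CPM (linear axis) in each resting, activated DMSO and activated TEPP-46 library, with the mean and SD of the 3 libraries as a bar and the replicate given by the marker. The 3 TEPP-46 libraries lie close together for Slc2a3 (347 ± 13.2 CPM), while among them Pkm, Ldha and Mki67 are highest in replicate 1.

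The largest falls with TEPP-46 by log2 fold change were in Nupr1 (57.1 ± 14.5 to 0.75 ± 1.03 CPM, -6.02 ± 0.85, adjusted p = 0.00315), Lta, Batf3 (63.2 ± 13.5 to 1.61 ± 2.00 CPM, -5.14 ± 0.68, adjusted p = 0.00252), the phospholipid acyltransferase gene Mboat2 (-5.05 ± 0.72, adjusted p = 0.00317), the heat shock gene Hspa1a (-4.97 ± 1.31, adjusted p = 0.0307) and the calpain gene Capn5 (-4.59 ± 0.61, adjusted p = 0.00259). Hspa1a stood at 4.42, 69.8 and 20.4 CPM in control replicates 1, 4 and 5, and its call was lost without control replicate 4 or 5 or TEPP-46 replicate 4 or 5 (highest adjusted p = 0.103). The largest rises included Ifit1bl1, a gene related to interferon-induced genes, which returned from 0.49 ± 0.41 to 39.1 ± 11.8 CPM (6.22 ± 0.47, adjusted p = 0.000293) against 53.3 ± 7.49 CPM in resting cells, and the zinc finger gene Zscan10, 85.2 times higher (95% counting interval 28.7 to 416, adjusted p = 0.00158). The others were Pf4, the platelet factor 4 gene (0 counts in control cells, at least 219-fold higher, adjusted p = 0.00681), Mpo (at least 86.8-fold, adjusted p = 0.0406), the metalloproteinase inhibitor gene Timp3 (128 times, 34.9 to 1060, adjusted p = 0.00861) and Mef2c, a transcription factor gene (92.1 times, 31.1 to 450, adjusted p = 0.0182). These 4 were highest in TEPP-46 replicate 4, where Pf4 stood at 154, Mpo at 86.1, Timp3 at 64.3 and Mef2c at 82.8 CPM, against 9.08, 0.83, 2.75 and 1.93 in replicate 1 and 45.6, 1.94, 15.2 and 7.44 in replicate 5. The Mef2c call was lost without any control library (highest adjusted p = 0.0802) and that of Mpo without any library but TEPP-46 replicates 1 and 4 (highest adjusted p = 0.108).

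Of the 22 glycolysis genes, 7 fell with TEPP-46 and 0 rose (14 within the list, median -1.18, camera adjusted p = 7.8e-08, 0.33 estimated). Pgam1 (-1.69 ± 0.32) and Gpi1 (-1.21 ± 0.25) fell. The mean log2 change of the list was -0.47, -2.19 and -1.47 in TEPP-46 replicates 1, 4 and 5. Of 17 hypoxia genes, 10 fell and 0 rose (13 within the list, median -1.46, camera adjusted p = 4.42e-08, 0.266 estimated). Among them were Ero1l at -3.24 ± 0.34 and Egln3 at -3.37 ± 0.44 (177 ± 23.5 to 16.8 ± 10.7 CPM). In the list of MYC-linked ribosome biogenesis, 13 of 26 genes fell and 0 rose (15 within the list, median -0.89, camera adjusted p = 7.8e-08, 0.33 estimated). The nucleolar genes Nop16 (-1.68 ± 0.24), Nop56 (-1.28 ± 0.21) and Nop58 (-1.31 ± 0.24) fell, and their levels of 23.1 ± 4.54, 151 ± 38.0 and 84.4 ± 22.4 CPM lay below those of resting cells (52.2 ± 9.10, 309 ± 12.6 and 153 ± 28.8). Amino acid response genes fell in 14 and rose in 1 of 24 cases (21 and 1 within the list, median -1.48, camera adjusted p = 1.62e-09, 0.33 estimated). They included the tRNA synthetase gene Eprs (-1.40 ± 0.25), and the exception was the tryptophanyl-tRNA synthetase gene Wars (0.92 ± 0.18). Serine, folate and nucleotide synthesis genes fell in 8 of 21 cases with 0 rises (14 within the list, median -1.10, camera adjusted p = 7.8e-08, 0.34 estimated). Shmt2 stood at -1.76 ± 0.37 and Ctps at -1.94 ± 0.44. Gpi1 lost its call without control replicate 4 or 5 or TEPP-46 replicate 5 (adjusted p up to 0.0655), Wars without control replicate 4 or 5 (up to 0.0711), Shmt2 without control replicate 1 or 5 (up to 0.0623), and Ctps without any control library or TEPP-46 replicate 5 (up to 0.071).

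Cell division genes were lower as a list in camera but not in fry (adjusted p = 0.0541), while single members mostly missed the threshold. Of 31 genes, 1 fell and 0 rose (0 within the list, median -1.45, camera adjusted p = 1.21e-08, 0.448 estimated). The exception was Cenpf (-1.91 ± 0.57, adjusted p = 0.0462), whose call was lost in each fit without a library other than TEPP-46 replicate 1 (highest adjusted p = 0.138). Mki67 stood at 188, 33.6 and 25.6 CPM in TEPP-46 replicates 1, 4 and 5 (-1.91 ± 0.61, adjusted p = 0.0552), and the list mean was -0.25, -2.98 and -2.87 in these libraries. Interleukin-2 and STAT5 targets fell in 5 and rose in 1 of 17 cases (9 and 1 within the list, median -1.21, camera adjusted p = 0.000162, 0.33 estimated). Socs2 fell (-2.31 ± 0.36). Lta was the only call among 10 cytokine and chemokine genes (1 fall; 1 rise and 1 fall within the list, median -1.13, camera adjusted p = 0.00748, 0.33 estimated). Early activation genes had 4 falls and 1 rise among 27 (4 and 1 within the list, median -0.51, camera adjusted p = 0.0253, 0.33 estimated). Tfrc stood at -1.72 ± 0.41 and Jun at 1.41 ± 0.38. Cholesterol synthesis had 2 falls among 22 (0 within the list, median -0.93, camera adjusted p = 0.000129, 0.497 estimated), in Stard4 and the lanosterol synthase gene Lss. The list mean was -0.04 in TEPP-46 replicate 1 and -1.77 and -1.64 in replicates 4 and 5. The TCA cycle had 3 falls among 21 (3 within the list, median -0.52, camera adjusted p = 0.00748, 0.526 estimated), among them the pyruvate carboxylase gene Pcx (-2.68 ± 0.73), and list means of -0.11, -1.02 and -0.66 in replicates 1, 4 and 5. Oxidative phosphorylation had 0 calls among 32 in edgeR, against 4 at an unadjusted p below 0.05, 3 falls in DESeq2 and 1 in limma-voom (0 within the list, median -0.26, camera adjusted p = 0.0327, 0.733 estimated), with list means of 0.24, -0.86 and -0.43. Heat shock and unfolded protein genes had 5 falls and 1 rise among 21 (8 and 1 within the list, median -0.64, camera adjusted p = 0.00748, 0.448 estimated). The chaperone gene Hyou1 fell (-0.85 ± 0.20) and Dnajb9 rose (1.40 ± 0.33). The camera call of early activation was lost without TEPP-46 replicate 4 (adjusted p = 0.0716) and that of oxidative phosphorylation without TEPP-46 replicate 4 or 5 (up to 0.526). Of the genes named here, Tfrc, Jun, Stard4, Lss, Pcx, Hyou1 and Dnajb9 each lost their calls without control replicate 5 and without TEPP-46 replicate 5, and some also without other libraries, with adjusted p of up to 0.0898, 0.125, 0.114, 0.145, 0.111, 0.0893 and 0.0966 over all left-out libraries.

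Genes of the naive state and of T cell identity were higher with TEPP-46. Of 24 naive and quiescence genes, 13 rose and 0 fell (16 and 1 within the list, median 1.42, camera adjusted p = 1.2e-09, 0.171 estimated). The list mean was 1.07, 1.37 and 1.35 in replicates 1, 4 and 5. The costimulatory receptor gene Cd27 rose from 98.1 ± 41.1 to 619 ± 139 CPM (2.66 ± 0.33). Its level in resting cells was 334 ± 58.7 CPM, and the difference from TEPP-46 cells did not pass the test. Slfn2 (2.22 ± 0.29) and Btg2 (2.44 ± 0.33) rose as well. T cell identity genes rose in 6 of 16 cases with 0 falls (10 within the list, median 0.88, camera adjusted p = 4.54e-05, 0.34 estimated). Cd247 (1.54 ± 0.26) and the costimulatory receptor gene Cd28 (1.25 ± 0.22) rose. Th1 genes rose in 4 of 14 cases with 0 falls (6 within the list, median 0.73, camera adjusted p = 0.0029, 0.33 estimated). Cxcr3 rose from 6.96 ± 2.06 CPM to 44.8, 73.9 and 107 CPM in replicates 1, 4 and 5 (3.43 ± 0.36). The list mean was 1.30, 0.08 and 1.11 in replicates 1, 4 and 5. Of 24 type I interferon genes, 6 rose and 0 fell (8 and 1 within the list, median 0.41, camera adjusted p = 0.07), with Irf9 at 1.49 ± 0.19 and Ifit2 at 1.27 ± 0.23. Among 7 Th17 genes 2 rose (3 rises and 1 fall within the list, camera adjusted p = 0.11), the transcription factor gene Maf (2.87 ± 0.51) and the chemokine receptor gene Ccr6 (2.51 ± 0.66). Treg genes had 2 rises and 1 fall among 14 (2 and 1 within the list, median 0.03 with camera pointing down, adjusted p = 0.912), the rises being Foxp3 and the integrin gene Itgae (2.90 ± 0.84), whose libraries overlapped. The Th1 camera call was lost without TEPP-46 replicate 1 (adjusted p = 0.0526). Cd28 and Ifit2 lost their calls without control replicate 5 (adjusted p of 0.0514 and 0.0503), Ccr6 without any control library or TEPP-46 replicate 4 or 5 (up to 0.11), and Itgae in each fit without a library other than TEPP-46 replicate 1 (up to 0.142).

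Inhibitory receptor and anergy genes had 1 rise and 1 fall among 15 (2 and 1 within the list, camera adjusted p = 0.199). Dgka rose (2.44 ± 0.31) and the receptor ligand gene Cd200 fell (-1.64 ± 0.38), the latter lost without control replicate 1 or 4 or TEPP-46 replicate 5 (adjusted p up to 0.0741). Lag3 stood at 1220 ± 219 CPM against 858 ± 155 (0.51 ± 0.30, adjusted p = 0.256). The p53 and apoptosis list had 3 rises and 1 fall among 19 (3 and 2 within the list, camera adjusted p = 0.955, median -0.19 but mean 0.01 and camera pointing up). Its rises were the stress gene Sesn1 (1.46 ± 0.23), the death-promoting gene Bcl2l11 (2.36 ± 0.38) and Trp53inp1 (1.74 ± 0.30). The oxidative stress list had 0 rises and 1 fall among 17 (0 within the list, camera adjusted p = 0.938) and the xenobiotic list 2 rises and 0 falls among 6 (2 within the list, camera adjusted p = 0.691).

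In camera, markers of B cells and NK cells were higher as lists in the TEPP-46 than in the control libraries, while those of myeloid cells did not pass. The B cell list did not pass the fry test (adjusted p = 0.115). Of 15 B cell markers, 8 rose and 0 fell (9 within the list, median 2.80, camera adjusted p = 0.000465, 0.448 estimated). Their summed CPM was 1215, 2990 and 1105 in TEPP-46 replicates 1, 4 and 5 against 820 ± 144 in control libraries. Ighm rose from 230 ± 11.3 to 786 ± 111 CPM (1.77 ± 0.20, adjusted p = 0.00158), while Igkc stood at 5.78, 122 and 20.4 CPM in the 3 TEPP-46 libraries (3.75 ± 0.95, adjusted p = 0.0271), a call lost without any control library or TEPP-46 replicate 4 (highest adjusted p = 0.100). NK cell markers rose in 3 of 5 cases with 0 falls (3 within the list, median 2.08, camera adjusted p = 0.0251, 0.33 estimated). Among them were Klrd1, 158 times higher (95% counting interval 27.9 to 6300) and Klrk1 at 3.90 ± 0.65. That camera call was lost without TEPP-46 replicate 1 (adjusted p = 0.0763). The NK cell markers summed to 116 ± 20.3 against 110 ± 27.6 CPM. Myeloid markers had 3 rises and 1 fall among 10 (5 and 1 within the list, camera adjusted p = 0.50, summed CPM 193 ± 37.8 against 207 ± 36.2), including Lyz2 (3.79 ± 0.91), lost without control replicate 4 or 5 or TEPP-46 replicate 5 (adjusted p up to 0.0925). Both platelet and red cell markers tested rose (2 within the list), Pf4 and the integrin gene Itga2b (3.38 ± 0.85, adjusted p = 0.0259, lost without any control library or TEPP-46 replicate 4 or 5, up to 0.0974). Their summed CPM was 15.6, 267 and 79.8 in TEPP-46 replicates 1, 4 and 5. The median of these 2 genes was 7.22, or 5.58 with Pf4 at its bound. Among 2 neutrophil markers and 1 CD8 marker 0 passed in edgeR, DESeq2 or limma-voom (1 and 0 at an unadjusted p below 0.05, 1 and 0 rises within the list). Mitochondrially encoded genes had 1 rise among 7 (2 within the list, camera adjusted p = 0.202). Histone genes had 0 calls among 5 in edgeR, DESeq2 and limma-voom (0 at an unadjusted p below 0.05, 0 within the list, camera adjusted p = 0.938). Cytosolic ribosomal protein genes had 1 fall among 24 (0 within the list, median -0.40, camera adjusted p = 0.0159, 0.733 estimated), with list means of 0.40, -1.70 and -0.62 in TEPP-46 replicates 1, 4 and 5. That camera call was lost without TEPP-46 replicate 4 (adjusted p = 0.595).

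**Figure D3:**
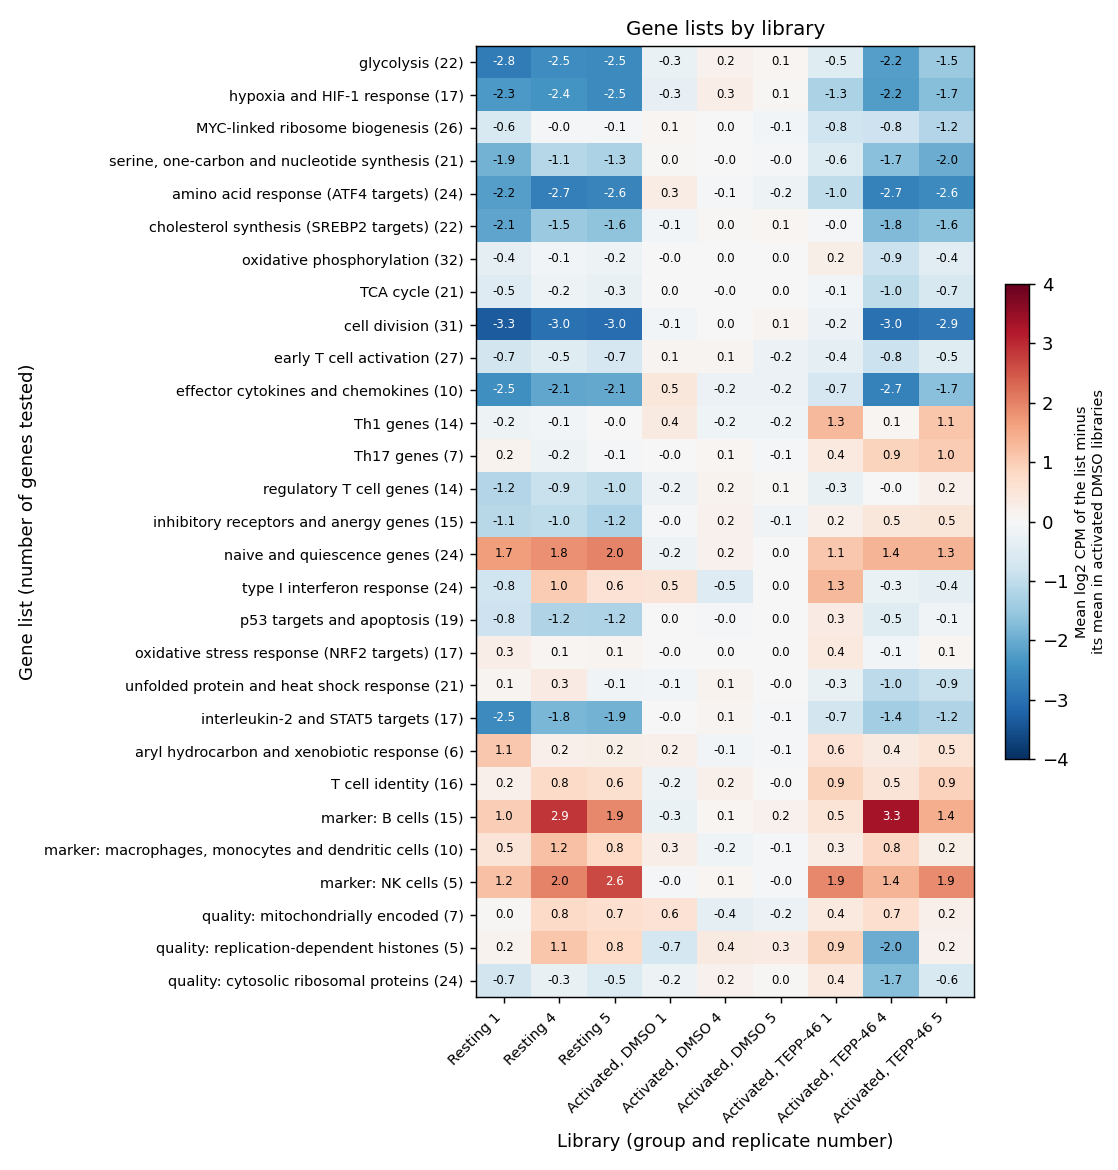
Mean log2 CPM of each of 29 gene lists in each library, minus the mean of that list in the activated DMSO libraries, with blue for lower and red for higher values and the number of genes tested in parentheses. Cell division genes stand at -0.25 in TEPP-46 replicate 1 and at -2.98 and -2.87 in replicates 4 and 5, while naive and quiescence genes stand at 1.07, 1.37 and 1.35.

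Camera called 19 of the 29 lists between TEPP-46 and control cells, 5 up and 14 down, and fry called 13. Lists called by camera but not by fry were heat shock, cell division, the TCA cycle and cholesterol synthesis (fry adjusted p of 0.0524, 0.0541, 0.0704 and 0.0896). So were B cell markers, oxidative phosphorylation and cytosolic ribosomal proteins (0.115, 0.3275 and 0.357). In turn, fry called the Th17 list up (fry adjusted p = 0.02185), which camera did not call. With an estimated correlation 0 of the camera calls held (2 lists at an unadjusted p below 0.05). Of 106 named genes called in this comparison, 43 kept the call in all 9 fits that left out a library. The calls lost were 51, 54 and 59 without control replicates 1, 4 and 5, 1, 26 and 49 without TEPP-46 replicates 1, 4 and 5, and 5, 14 and 15 without resting replicates 1, 4 and 5. Genes that kept the call included Slc2a3, Hk2, Pgam1, Egln3, Ero1l, Nop16, Nop56, Nop58, Nupr1, Lta, Batf3 and Socs2 among the falls and S1pr1, Cd27, Slfn2, Btg2, Txnip, Cxcr3, Maf, Irf9, Dgka, Cd247 and Ighm among the rises.

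Genes called in both comparisons mostly changed in opposite directions. Of the 1938 genes that rose with activation, 529 (27.3%) fell with TEPP-46 and 16 rose further, and of the 1976 that fell, 777 (39.3%) rose and 2 fell further. Hk2, Egln3, Lta, Socs2 and Il2ra were among the first and S1pr1, Txnip, Cxcr3 and Dgka among the second. Independent lists of the same sizes would share 125 and 192 genes in the opposite and 188 and 127 in the same directions. Both comparisons use the same control libraries. The 20 simulations without a TEPP-46 effect called at most 1 gene with TEPP-46, so their overlaps say nothing, and only their fold changes are used. Over all genes, which are not independent replicates, the log2 fold changes of both comparisons had a Pearson r of -0.70 (simulated mean -0.13) and a covariance of -1.30 (simulated mean -0.11, range -0.14 to -0.09, difference -1.19). With the control libraries split so that the comparisons shared none (6 ways), the covariance was between -1.33 and -1.27. The opposite overlaps were then 88 to 112 and 99 to 149 genes with 2 control libraries against TEPP-46, and 1 to 4 and 3 to 6 with 1. TEPP-46 replicates 1, 4 and 5 kept a median of 70.1%, 28.4% and 29.5% of the activation change in genes that rose and 56.9%, 31.5% and 24.8% in genes that fell. The 2 opposite overlaps were 335 and 506 genes without resting replicate 4, 368 and 520 without resting replicate 5, and 166 and 261, 121 and 260 or 99 and 187 without control replicate 1, 4 or 5. They were 1373 and 1382 without TEPP-46 replicate 1, and 162 and 309 without TEPP-46 replicate 5.

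**Figure D4:**
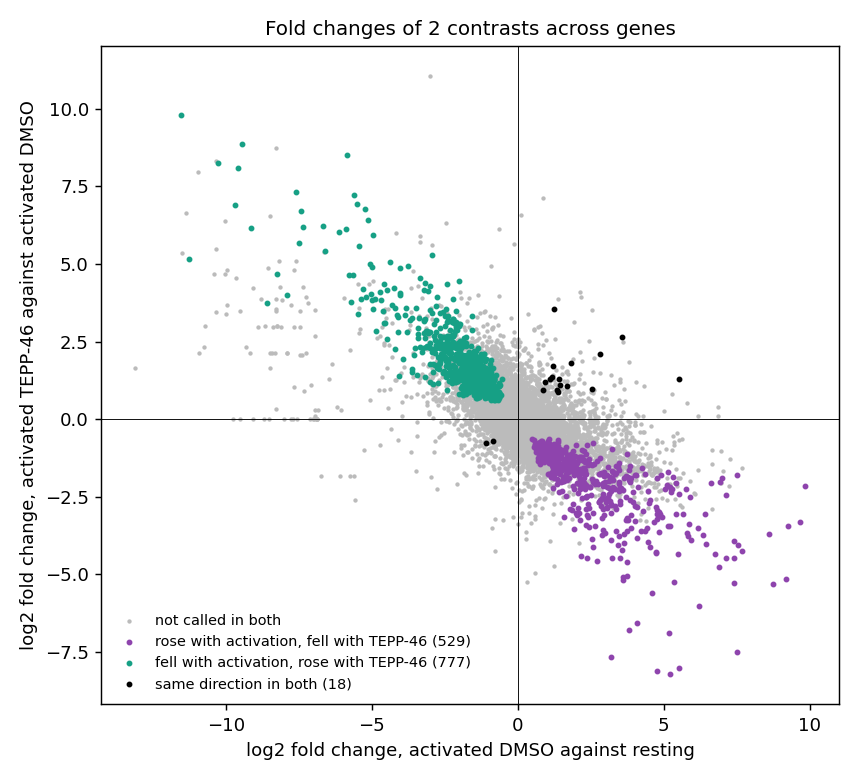
Log2 fold change of each of 12536 genes with activation (control against resting, horizontal) and with TEPP-46 (TEPP-46 against control, vertical), with coloured points for genes called in both comparisons. Of these, 529 lie at the lower right, 777 at the upper left and 18 in the same direction in both; fitted fold changes of genes without counts in a group depend on the prior count.

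Compared with resting cells, TEPP-46 cells showed part of the activation profile. Hk2 (3.02 ± 0.48, adjusted p = 0.00543), Il2ra (3.45 ± 0.47, adjusted p = 0.00276), Hif1a (2.84 ± 0.40, adjusted p = 0.00316) and Tbx21 (3.66 ± 0.63, adjusted p = 0.00813) were higher. Cd69 was lower (-1.64 ± 0.40, adjusted p = 0.0313), a call lost without resting replicate 4 or 5, any control library or TEPP-46 replicate 5 (up to 0.105). Pkm (1.23 ± 0.39, adjusted p = 0.0715), Ldha (1.04 ± 0.45, adjusted p = 0.170), Slc2a1 (0.72 ± 0.26, adjusted p = 0.110), Foxp3 (0.45 ± 0.31, adjusted p = 0.392), Il2 (0.97, adjusted p = 0.578), Ifng (-2.44 ± 0.81, adjusted p = 0.0848), Myc (-0.29 ± 0.62, adjusted p = 0.812) and Txnip (-0.12 ± 0.31, adjusted p = 0.849) did not pass in edgeR. In all, 798 genes rose and 491 fell, with full separation in 26.8% of genes where chance gives 10%. These 1289 calls became 400 when only the 2 groups were fitted and 2090 with DESeq2. The number of calls was 451 or 426 without resting replicate 4 or 5 and 833, 770 or 750 without control replicate 1, 4 or 5. Camera called 13 lists, 10 up and 3 down, of which 0 held with an estimated correlation (3 at an unadjusted p below 0.05). Of the list members, 9 of 22 glycolysis genes and 9 of 31 cell division genes rose with 0 falls (15 and 19 within the list, camera adjusted p of 1.53e-07 and 3.75e-05, 0.414 and 0.895 estimated). Of 15 inhibitory receptor and anergy genes 6 rose and 0 fell (8 within the list, camera adjusted p = 2.08e-07, 0.0875 estimated). Of 26 genes of MYC-linked ribosome biogenesis 8 fell and 0 rose (12 within the list, camera adjusted p = 1.65e-06, 0.40 estimated). Naive and quiescence genes had 1 rise and 5 falls among 24 (3 and 6 within the list, camera adjusted p = 0.0476, 0.587 estimated).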

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

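Library quality weights, thinning to equal totals, the length and GC trend, TMM factors without abundant genes and the split of the control libraries were chosen after the data had been seen; the other settings were planned. The numbers of genes called for activation, TEPP-46 against control and TEPP-46 against resting cells (3914, 2025 and 1289) stayed within 1.5 times with DESeq2 size factors, total counts, no filter (4260, 2548 and 1750), a stricter filter (3715, 2001 and 1188), thinning (3527, 1933 and 1091), the length and GC trend (4170, 2188 and 1380) and TMM factors without abundant genes (3906, 2023 and 1277). DESeq2 called 3057 genes for TEPP-46 against control, 2090 against resting cells and 927 that rose with activation and fell with TEPP-46; limma-voom gave 842 of the latter. A threshold of 2-fold (glmTreat) left 1183 genes for activation and 182 for TEPP-46. Library weights, which were 0.218 and 0.255 for TEPP-46 replicates 1 and 4, 0.274 for resting replicate 1 and at least 1.18 for the others, gave 7315, 6164 and 3360 genes and overlaps of 2174 and 2098. A fit of only the groups compared gave 5739, 1450 and 400 genes. The main fit shares its estimate of spread over groups with a median SD of log2 CPM of 0.52 (TEPP-46), 0.31 (resting) and 0.20 (control). Its p-values for comparisons with TEPP-46 may therefore be too small. With an estimated inter-gene correlation, 0 of 15 lists for activation and 0 of 19 for TEPP-46 held. The cause of these shifts was not tested. With control replicate 1, 4 or 5 alone for activation and the other 2 for TEPP-46, the opposite overlaps were 109 and 149, 112 and 102, or 88 and 99 genes. With replicate 1, 4 or 5 alone for TEPP-46 they were 1 and 3, 4 and 6, or 2 and 4. Fewer control libraries enter each comparison there. No label states that equal replicate numbers mark the same mouse or day. Same-numbered libraries correlated by -0.123 to 0.0893 in their deviations from the group mean (9 pairs), others by -0.108 to 0.123. Thus no pairing was seen in this measure, which does not exclude a shared day or mouse. With the replicate block, 3339, 1384 and 705 genes were called. Leaving out each library in turn gave 2316 to 5194 genes for activation, 395 to 4407 for TEPP-46 against control and 426 to 1897 against resting cells, overlaps of 99 to 1373 and 187 to 1382, and 13 to 16 and 17 to 21 lists. The lowest numbers of genes came without control replicate 5 for activation, TEPP-46 against control and both overlaps, and without resting replicate 5 for TEPP-46 against resting cells. Signs turned only for genes that were not called. Over the left-out libraries and against resting cells these were Txnip (-0.359 to 0.0687), Myc (-1.23 to 0.265) and Il2 (-0.0474 to 1.79). Against control cells they were Ifng (-1.77 to 0.542), Tbx21 (-0.259 to 1.03) and Cd69 (-0.896 to 0.044). With library weights Il2 stood at -2.23 and Txnip at 0.277 against resting cells, and after thinning Ifng stood at 0.0333 against control cells; the cause was not tested. Of the other values of named genes, 2973 kept direction and side of the threshold, 113 lost and 17 gained the call under the settings that keep all libraries, and 1912, 416 and 10 without a library. Simulated data with few changed genes gave back 3%, 5% and 4% of 2-fold changes, so uncalled genes may still differ. Limma-voom with library weights called 6164 genes for TEPP-46 where 2025 were called in edgeR. That fit rested mostly on 1 treated library, as the weights were 2.3 for TEPP-46 replicate 5 and 0.218 and 0.255 for replicates 1 and 4.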

Other observations

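The tests of shared control libraries, of a mixture of cells, of a covariate unrelated to the groups, of carried-over B cells and of a lower share of T cells were chosen only after the results they address had been seen. Those of carried-over B cells and of a lower share of T cells for the platelet genes replace earlier forms that had ended differently, and those of shared control libraries and of a mixture replace forms that had ended alike. TEPP-46 cells also held transcripts that lay outside both other groups. Of the 2025 genes called against control cells, 175 were above and 65 below both control and resting cells, each at an edgeR quasi-likelihood Benjamini-Hochberg adjusted p below 0.05, together 11.9%. Above and below, the counts were 60 and 14 or 62 and 13 without resting replicate 4 or 5, and 61 and 16, 57 and 15 or 44 and 13 without control replicate 1, 4 or 5. They were 472 and 327 without TEPP-46 replicate 1 and 74 and 20 without TEPP-46 replicate 5, and the share ranged from 4.94% without resting replicate 4 to 18.1% without TEPP-46 replicate 1. The genes in these 2 paragraphs were chosen after their values were seen. The metallothionein gene Mt2, which encodes a metal-binding protein, stood at 107, 69.7 and 125 CPM in TEPP-46 replicates 1, 4 and 5, against 1.97 ± 0.46 in control and 2.17 ± 0.19 in resting libraries (log2 fold change 5.65 ± 0.34 against control, adjusted p = 4.82e-05). Its neighbour in the gene family, Mt1, stood at 336, 234 and 422 CPM against 28.1 ± 3.73 and 11.8 ± 8.01 (3.55 ± 0.43, adjusted p = 0.00206). The glycoprotein gene Gpnmb rose to 65.4 ± 26.7 CPM from 2.13 ± 1.01 in control and 3.98 ± 1.64 in resting libraries (4.92 ± 0.53, adjusted p = 0.00139). Below both groups were Trat1, a T cell receptor adaptor gene (3.38 ± 2.62 CPM against 39.9 ± 7.42 and 73.5 ± 43.9), the kinase gene Camkk1 (1.52 ± 1.46 against 14.6 ± 2.38 and 16.3 ± 1.89) and the folate enzyme gene Fpgs (8.62 ± 3.10 against 26.7 ± 2.22 and 27.1 ± 2.98), with changes against control of -3.50 ± 0.60, -3.16 ± 0.61 and -1.61 ± 0.31. All TEPP-46 libraries of these 6 genes were separated from the control and the resting libraries. Each call against either group held without any 1 library, except that of Fpgs against resting cells without resting replicate 5 (adjusted p = 0.0513).

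Some genes were at similar levels in the 3 TEPP-46 libraries and others were not. Slc2a3 stood at 362, 337 and 342 CPM in replicates 1, 4 and 5, and Ifi209, an interferon-inducible gene, at 273, 228 and 270 CPM against 8.51 ± 1.01 in control and 273 ± 65.5 in resting libraries. Gzmb stood at 361, 48.7 and 54.4 CPM, Mki67 at 188, 33.6 and 25.6, and the protease inhibitor gene Serpina3f at 540, 42.0 and 33.3.

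The first pattern is that 1306 genes moved by activation lay back towards resting levels with TEPP-46. Shared control libraries would leave little covariance of the fold changes once no control library was in both comparisons, but it was -1.33 to -1.27 in the 6 such splits, against -1.30 with all libraries. Intact cells like those of the resting and control libraries, mixed together, would leave no gene beyond both groups. A joint test (the larger p of both comparisons, adjusted) placed 18 there by more than 2-fold. The number was 6 or 3 without resting replicate 4 or 5 and 1, 6 or 1 without control replicate 1, 4 or 5. It was 187, 28 or 4 without TEPP-46 replicate 1, 4 or 5. Mixing of such cells alone thus does not account for all of the pattern. Unactivated cells unlike the resting libraries, or carried-over cells of other types, could also place genes beyond both groups, so the test cannot exclude those. After thinning to equal totals 1234 genes were called as moved back, 1133 of them among the 1306, so library totals do not account for all of it. With log2 Malat1 as a covariate for nuclear RNA, the median changes went from -1.67 to -1.42 (median SE 0.38 and 0.377) and from 1.47 to 1.23 (0.303 and 0.307), at least 83.7% of their size. Of 529 and 777 genes, 211 and 340 were still called, against 352 to 529 and 567 to 775 with a covariate unrelated to the groups (20 draws). In total 776 genes were called with Malat1, against 1291 to 2680 in these draws. Malat1 thus took more calls than any of the draws, and the cause was not tested. A candidate explanation is that TEPP-46 limits part of the activation programme. A toxic or off-target effect and a difference in timing stay open and untested. So does a mixture combined with a treatment effect or with cells unlike those of the resting libraries.

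The second pattern is that TEPP-46 replicate 1 lay nearer to the control libraries than replicates 4 and 5. Were it a mislabelled control library, it should lie beyond every control library in about 25% of the genes that replicates 4 and 5 place outside both groups. It did so in 70.8% (566 of 799). The 25% is only a rough mark. The same control libraries helped to choose these genes, which would raise it by an amount not measured. Genes within a library also move together. Depth does not remove the gap between replicates 1 and 5 in the activation change kept, which went from 40.7 to 40.5 percentage points on thinning in genes that rose and from 32.0 to 34.3 in genes that fell. Carried-over B cells in place of T cells would lower T cell identity genes as much as cell division genes, but replicates 4 and 5 differed from replicate 1 by -0.37 and 0.03 in the first list mean and by -2.73 and -2.62 in the second (SD of the first 0.202 in control libraries), so they do not account for the gap, although replicate 4 had the most B cell markers. A different concentration within the 50 to 100 µM range, or a different culture or day, may have set the libraries apart, but the labels give no such value per library, and no test of it was possible. Replicates 4 and 5 were also the most alike pair in the resting and control groups, with a chi-square per degree of freedom of 9.49 and 4.03. Pairs with replicate 1 gave 41.55 and 44.66 (resting), and 9.89 and 7.88 (control). An effect tied to the replicate number therefore stays open.

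The third pattern is that markers of platelets, B cells and NK cells were higher in TEPP-46 than in control libraries, although with an estimated correlation the B and NK cell lists did not pass (adjusted p of 0.448 and 0.33), and the NK cell call was lost without TEPP-46 replicate 1 (0.0763). The B cell list did not pass the fry test either (adjusted p = 0.115). A lower share of T cells would raise the markers of all other cells alike, but summed CPM went from 3.76 to 121 for platelet, 820 to 1770 for B cell, 110 to 116 for NK cell and 207 to 193 for myeloid markers, among them Batf3 at -5.14 and Lyz2 at 3.79, and the CD8 T cell marker Cd8b1 stood at -0.77 ± 0.65. These values do not exclude it, since genes of at least 5 CPM in control libraries, which hide a small share of other cells, made up 97.2%, 93.9% and 97.5% of the control sums of the B cell, NK cell and myeloid lists, and below 5 CPM the medians were 3.87, 2.99 and 3.45 (median SE 1.01, 0.807 and 1.19). Over all members the medians of 2.80, 2.08 and 2.31 lay within 0.72 of each other (median SE 0.798). The platelet median, with Pf4 at its bound, exceeded that of B cells by 2.78 (largest SE 1.70). Medians known beforehand do not count for a lower share. T cell identity genes, which a lower share alone would lower, had mean log2 changes against control of 0.89, 0.52 and 0.92 in TEPP-46 replicates 1, 4 and 5. Their direction is opposite, but 6 of these 16 genes fell with activation itself. A return of these genes towards resting levels could hide a small loss of T cells. A lower share therefore cannot be told apart from other causes. Ighm and Klrd1 were higher in all 3 TEPP-46 libraries, the NK cell list mean was lowest in replicate 4 (1.36), where that of B cells was highest (3.33), and whether such transcripts come from carried-over cells, which the magnetic sorting should largely remove, or from T cells may need single-cell data.

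Other splits of the samples are too few to give a share under 0.05 for any result. The real groups gave 3914 genes for activation, 2025 for TEPP-46 against control and 1289 for TEPP-46 against resting cells, and the highest of the other splits gave 0, 0 and 5 (1 of 10 splits as large in each). For gene lists the real values were 15 and 19, with 16 and 17 as the highest of the others (3 and 1 of 10). For the 2 opposite overlaps they were 529 and 777, with 175 and 65 (1 of 20 each). The 175 and 65 came from the real groups with the control and TEPP-46 labels swapped, and are the genes above and below both other groups. Each assignment that mixed the control and TEPP-46 libraries gave 0 and 0.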
